A study of Mus musculus with 5 samples.

How the data were processed

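Chromatin was prepared from freshly dissected brain, kidney, liver, lung and spleen of adult FVB mice, with 1 library per tissue. Per the labels' protocols, tissue was crosslinked with 1% formaldehyde for 10 min, the reaction was stopped with 0.125 M glycine, chromatin was sheared to 0.2 to 0.8 kb, 10 µg of an antibody against RNA polymerase II from Abcam was used, and 10 ng of the purified DNA went into each Illumina library. No input or control library was used here.

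The authors deposited 2 files per tissue. One lists aligned reads, 1 per line with chromosome, start, end and strand; per the submitters' processing notes, Bowtie was used, and its version, its settings for mismatches and for reads with several hits, and the genome build are not given in the sources used here. The other is the authors' list of peaks for that library, each given as a single position on a grid of 5 bp with no width, score or p-value; the caller, its threshold and any control are not given in the sources used here. Nearly all reads were 35 bases long, and lines of a length outside 34 to 36 bases, 4 to 15 per library, were left out. The listed reads lay on the 19 autosomes, X and Y.

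A table of mouse genes on assembly GRCm38 was used only to compare chromosome extents. On chromosome 7 the last aligned read lay at 152524509 in the deposited coordinates, past the end of the last gene on that chromosome in the table, so the builds differ; coordinates were not converted and the table was not used to name genes. Before the data were examined, the tests, the alternatives, the lists of tissue marker genes and the rule for named items were fixed, including the rule that without an annotation of the files' build the comparison of promoters is made on peak regions and reported by position. The gene lists, gene-body reads and promoter sequence were therefore not analysed here. The number of regions in 1 to 5 tissues was among these planned results. Runs, regions high in a pair of tissues, read ratios and examples at regions common to all tissues, and the contrast of centre over flank density between common and restricted regions were added after the data were seen.

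Each peak position was extended by 250 bp to both sides, and overlapping windows of all tissues were merged into regions. A tissue has a peak in a region when 1 of its positions falls in it, and regions count as shared with any overlap of at least 1 bp. Chance sharing came from 100 circular shifts of each list along each chromosome. Reads were counted once, at their 5′ end, as deposited. Scaling factors were medians of ratios over 8222 regions with at least 20 reads in every tissue: 1.03 for brain, 1.09 for kidney, 1.17 for liver, 1.13 for lung and 0.671 for spleen. Factors from total reads were 0.823, 1.10, 1.20, 0.867 and 1.06. The difference between these scalings on the log2 scale was 0.33 for brain, -0.01 for kidney, -0.03 for liver, 0.39 for lung and -0.66 for spleen.

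A restricted region held at least 20 reads in its tissue and at least 4 times the normalised count of each other tissue, with counts under 3 set to 3. Fold intervals are 95% exact conditional binomial (Clopper-Pearson) intervals of the raw counts, and shares have exact binomial intervals. The named regions are the 5 per tissue with the largest fold among restricted regions with at least 50 reads. For regions whose next highest tissue was under 3 reads, read counts are given and no fold. Named runs are the 3 per tissue with the most regions, of which some are given, and named pairs of adjacent regions are among the 8 with the largest difference in share, at least 50 reads of the pair in both tissues. Runs join restricted regions with gaps of up to 5 kb. Centre over flank density compares the 250 bp to both sides of a region's midpoint with the sequence 1 to 5 kb away, with 1 read added to both for medians over regions.

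No p-value was computed, since each tissue had 1 library. The calling of restricted regions was tested on simulated data drawn from the 186413 real regions. Of 50 regions each with a simulated fold of 2, 4, 6 and 8, 0%, 16%, 94% and 100% were called. Of 40687 unchanged regions, 0 were called. The simulated counts held counting error only, around a mean shared by all tissues, so they leave out variation between libraries. Changed regions came from those with a mean of at least 20 normalised reads, so regions with fewer reads were not tested. The shares of reads that repeat the position and strand of another read were 7.12% in brain, 4.51% in kidney, 8.87% in liver, 7.16% in lung and 8.52% in spleen. Alternatives covered the overlap rule, the number of peaks, scaling, repeated reads, window size, read position, background, depth, read minimum and fold. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.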

Results

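RNA polymerase II was mapped by chromatin immunoprecipitation and sequencing in 5 tissues of adult FVB mice: brain, kidney, liver, lung and spleen. The question set by the design was which promoters are active in which tissue. Each tissue was represented by 1 library, so there were no replicates and no test between tissues. Intervals of folds and of shares of reads cover counting error only and treat each read as an independent molecule. Sequencing reads without molecular identifiers are not independent molecules, so these intervals may be too narrow even for counting error. Bootstrap intervals and intervals of a median give the precision of a summary over regions, not the spread of single regions. No interval here covers differences between animals. The libraries held 10292262 aligned reads for brain, 13786536 for kidney, 14964934 for liver, 10846976 for lung and 13283124 for spleen. The genome build behind the coordinates is not given in the sources used here, so regions are named by deposited chromosome and position, and no gene, exon or promoter annotation was attached to them.

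Brain had the most polymerase peaks, 91712, and spleen the fewest, 31594. Kidney had 81375 peaks, lung 72971 and liver 57816. In brain, 14.4% of reads (95% exact binomial interval 14.4% to 14.5%) lay within 250 bp of a brain peak, against 12.4% in lung, 11.9% in kidney, 11.4% in liver and 4.57% (4.56% to 4.58%) in spleen. Spleen peaks were also the most widely spaced, at a median of 15510 bp from one to the next, whereas the medians of the other tissues ran from 2250 bp in kidney to 3000 bp in lung. The peak lists covered 45.8 Mb in brain and 15.8 Mb in spleen when each position was extended by 250 bp to both sides. At the regions with a peak in all 5 tissues, leaving out 4 pile-up regions with very many reads in every library, read density in the central window over that in the flanks from 1 to 5 kb away was 5.54 in brain (95% bootstrap interval over regions 5.29 to 5.76), 5.53 in lung (5.24 to 5.74), 5.19 in liver (4.84 to 5.53), 4.17 in kidney (3.95 to 4.38) and 3.84 in spleen (3.33 to 4.31). Kidney and spleen were not separated beyond this interval.

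Most regions held a peak in a single tissue, and a smaller set was common to all. The threshold of the peak lists is not given, and a region without a peak in a tissue can still hold its reads. Merging the peaks of the 5 tissues gave 186413 regions, of which 123556 (66.3%) had a peak in 1 tissue, 31432 in 2, 14455 in 3, 8329 in 4 and 8641 (4.64%) in all 5. Of brain regions, 49.0% also had a peak in at least 1 other tissue, while this share was 59.7% in liver, 62.4% in spleen, 64.0% in kidney and 67.1% in lung. When the peak positions of each tissue were shifted along each chromosome at random 100 times, the highest such share was 9.52% in brain, 10.2% in liver, 11.7% in spleen, 9.49% in kidney and 10.0% in lung, and no set of shifts gave more than 1 region in all 5 tissues. By the Jaccard index, kidney and lung had the most similar peak sets, at 0.303 with 32413 regions in common. Kidney and liver followed at 0.250, then brain and lung at 0.244, and brain and spleen had the lowest index, 0.137. The number of peaks per list limits these overlaps: with equal numbers of peaks per tissue, an alternative chosen after the data were seen, the lowest index was that of liver and spleen, 0.169, against 0.190 for brain and spleen, spleen had the lowest shared share, 45.7%, and brain reached 56.4%. The Spearman correlation of normalised read density across regions, which are not independent replicates, was also highest for kidney and lung, 0.411, but lowest for brain and liver, 0.0517, with 0.189 for brain and spleen.

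**Figure D1:**
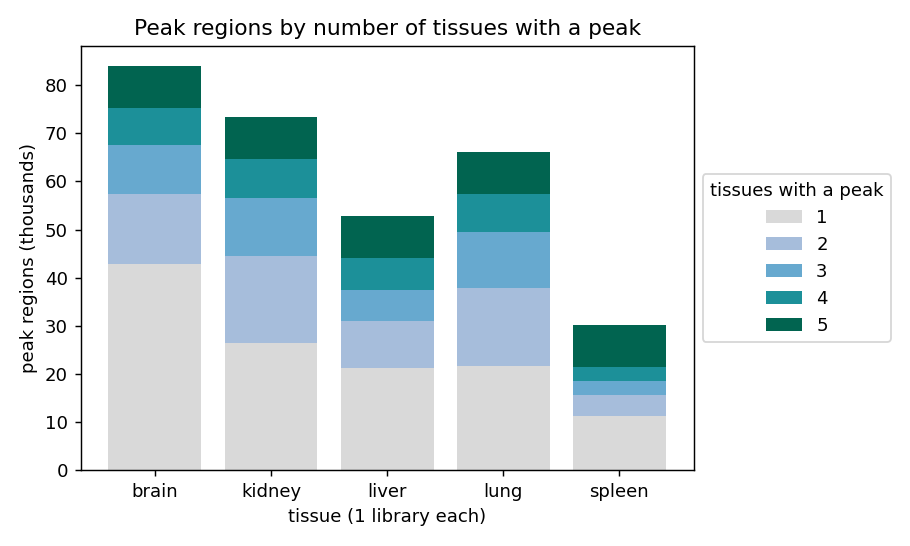
Number of merged peak regions in each tissue (vertical axis, in units of 1000; 1 library per tissue on the horizontal axis), with each bar divided by how many of the 5 tissues had a peak in the region. The 8641 regions common to all tissues form a band of equal height in each bar, and the regions found in 1 tissue make up the largest part, from 11328 in spleen to 42800 in brain.

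At regions with a peak in all 5 tissues, read number varied between the libraries. The median ratio of the highest to the lowest normalised read count across tissues was 2.17 (quartiles 1.75 and 2.84), 3506 of the 8641 regions (40.6%) stayed under 2-fold, and 843 (9.76%) reached 4-fold. Such a ratio lies above 1 by construction: with equal normalised reads in every tissue, counting error alone gave a median of 1.39 and at most 9 regions at 4-fold in 100 simulations, which leave out variation between libraries of 1 tissue. With scaling by total reads, an alternative chosen after the data were seen, the median ratio was 2.86, 1347 regions stayed under 2-fold and 1848 reached 4-fold. These regions made up 7.13% of the total region length and held 21.7% of region reads in brain, 19.5% in kidney, 24.1% in liver, 25.4% in lung and 23.5% in spleen. On chromosome 6, the region from 136752531 to 136753156 held 217 normalised reads in kidney, 222 in lung, 278 in brain, 292 in spleen and 319 in liver, a ratio of 1.47. On chromosome 10, the region from 127928456 to 127931181 ranged from 186 normalised reads in spleen to 365 in lung. Among regions under 2-fold, these ranked next after the first by their lowest normalised count, a ranking chosen after the data were seen. The first, on chromosome 11 from 3033541 to 3036141, lay 33.3 kb from the first aligned read of its chromosome and had its highest count, 576, in spleen.

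Among regions with at least 20 reads, the liver library had the most with polymerase reads restricted to it, and the most at 8-fold or more. A region was called restricted to a tissue when it held at least 20 reads there and at least 4 times the normalised count of the next highest tissue. This gave 3649 regions in liver, 1514 in kidney, 1068 in brain, 609 in spleen and 217 in lung, 7057 in all. Regions with at least 20 reads numbered 34155 in liver, 38312 in kidney, 27125 in brain, 13528 in spleen and 26999 in lung. As a share of these, liver was still highest and lung lowest, but spleen lay above kidney and brain. At least 8-fold were 1082 regions in liver, 131 in spleen, 108 in kidney, 75 in brain and 20 in lung. Of regions with a peak in 1 tissue alone, 3144 of 21277 in liver and 1318 of 26409 in kidney were restricted to it. So were 1002 of 42800 in brain, 473 of 11328 in spleen and 148 of 21742 in lung. These totals include regions with under 20 reads, which cannot be called restricted. With at least 20 reads in the central window, regions with a peak in 1 tissue alone numbered 6864 in liver and 4498 in kidney. In brain there were 3163, in spleen 595 and in lung 1178. Many restricted regions lay side by side: neighbours within 5 kb counted as 1 place gave 1442 places in liver, 807 in kidney, 668 in brain, 517 in spleen and 118 in lung. With libraries scaled by total reads, the counts were 3850 in liver, 2144 in brain, 1433 in kidney, 572 in lung and 179 in spleen, and 3284, 1058, 1104, 217 and 179 regions of these were called under both scalings. Spleen was the next highest tissue for 691 of the 1068 brain regions, 868 of the kidney regions and 2260 of the liver regions. Low counts were raised to the same floor before scaling, and spleen had the lowest scaling factor, so these counts favour spleen. How many of them rest on the floor was not counted. Leaving spleen out raised the counts of restricted regions to 2017 in brain, 481 in lung, 2186 in kidney and 4849 in liver. This alternative was chosen after the data were seen. With scaling by total reads, leaving spleen out gave 2478, 706, 1636 and 4123 in the same order, against 2144, 572, 1433 and 3850 with it. With no read minimum spleen led, at 4152 regions against 3649 in liver, but spleen had 393 with at most 1 read per position and strand and 324 after thinning to the smallest library, while background subtraction gave 1946 in brain and 393 in lung.

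**Figure D2:**
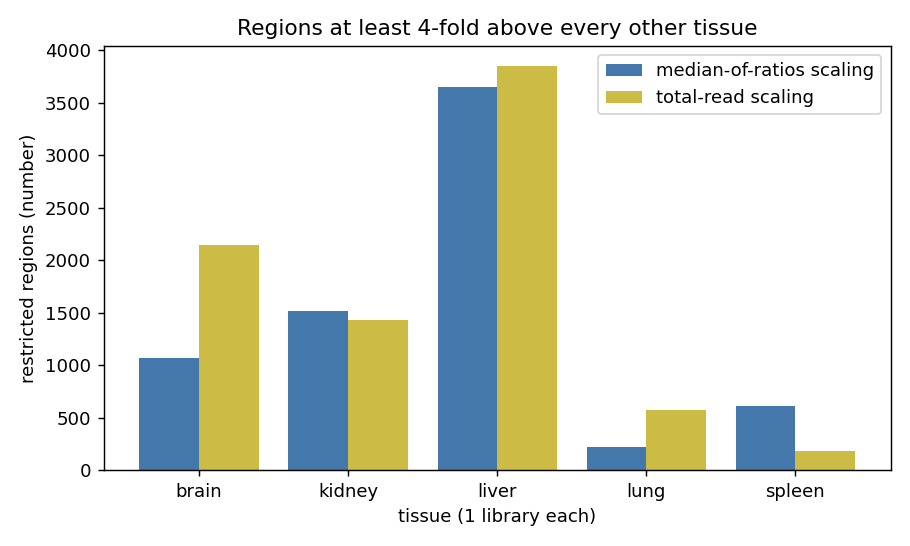
Number of regions (vertical axis) with at least 20 reads in a tissue and at least 4-fold the normalised count of every other tissue, for each of the 5 tissues (1 library each). Bars compare scaling by median of ratios with scaling by total reads: liver leads under both, at 3649 and 3850 regions, while spleen falls from 609 to 179 and lung rises from 217 to 572.

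In liver, the leading regions were almost empty elsewhere. The leading regions of each tissue were picked for the largest fold, and the intervals of their folds do not cover that choice. The region on chromosome 5 from 90895441 to 90895941 held 1198 liver reads and 6 in kidney, the next highest tissue, a normalised fold of 187 (95% interval 85.4 to 509). A second region on the same chromosome, from 90899241 to 90899741, held 1094 liver reads and 2 to 5 in the other tissues, 157-fold (61.1 to 577) over spleen. On chromosome 8, the region from 112514356 to 112514856 held 1143 liver reads and at most 4 elsewhere, 164-fold (63.9 to 603) over spleen. The region on chromosome 7 from 31727456 to 31728356 was 142-fold over spleen (55.1 to 520), with 986 liver reads. On chromosome 18, from 65409261 to 65409761, liver held 753 reads, kidney 2, brain and lung 1 each and spleen 0.

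The leading regions of the other tissues, picked in the same way, showed smaller folds. In brain, 2 of the 5 leading regions lay close together on chromosome 2: from 25144441 to 25144941, with 107 brain reads and 1 to 5 elsewhere, and from 25145791 to 25146291, 18.5-fold (9.51 to 41.3) over lung. The region on chromosome 13 from 54859551 to 54860051 was 24.4-fold higher in brain (9.32 to 90.6; 150 reads against 4 in spleen), that on chromosome 14 from 65208746 to 65209246 was 21.5-fold (9.58 to 59.8) over liver, and that on chromosome 1 from 50983996 to 50984496 was 18.7-fold (8.82 to 47.5) over kidney.

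In kidney, the region on chromosome 13 from 55500836 to 55501336 held 162 reads, 18.7-fold (9.60 to 41.6) over lung, and that on chromosome 2 from 69277021 to 69277971 was 16.6-fold (7.36 to 46.4) over lung. The kidney region on chromosome 14 from 21663066 to 21663566 held 77 reads against 1 to 4 in the other tissues. The region on chromosome 8 from 63003001 to 63003501 was 15.6-fold (5.13 to 77.2) over spleen, and that on chromosome 7 from 126704961 to 126705461 held 70 kidney reads and at most 2 elsewhere.

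In lung, the region on chromosome 4 from 94714881 to 94715381 was 13.8-fold (5.68 to 43.9) over brain. Lung regions on chromosome 15 from 101100386 to 101101081 and from 101101136 to 101101681 were 13.3-fold (8.01 to 23.7) and 11.2-fold (6.63 to 20.5) over kidney. The lung region on chromosome 5 from 53461586 to 53462086 was 12.3-fold (4.62 to 46.1), and that on chromosome 2 from 117942416 to 117942956 was 11.1-fold (4.96 to 31.0), both over spleen.

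In spleen, the region on chromosome 1 from 53848156 to 53848656 held 76 reads, 30.9-fold (11.6 to 116) over kidney. The spleen region on chromosome 10 from 42621186 to 42621686 was 20.01-fold (7.36 to 76.2) over brain, and that on the same chromosome from 59682641 to 59683141 was 13.4-fold (6.43 to 32.4) over kidney. On chromosome 9, from 105973951 to 105974451, spleen was 15.7-fold (8.17 to 33.8) over lung, and on chromosome 11, from 99016221 to 99016721, it was 13-fold (5.91 to 34) over lung.

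Part of the restricted regions lay in runs, with a median span of 8.44 kb in liver, 7.80 kb in kidney, 7.31 kb in spleen, 6.98 kb in brain and 4.80 kb in lung. A few were far longer. The longest, in kidney, spanned 161 kb of chromosome 2 from 69261121 to 69422471: it held 115 restricted regions and 10802 kidney reads, 6.81-fold (6.47 to 7.18) over lung. A liver run of 118 kb on chromosome 1 from 67162691 to 67280391 held 93 restricted regions and 16541 reads, 15.6-fold (14.4 to 17.0) over spleen. Runs of at least 3 restricted regions within 5 kb of each other numbered 310 in liver, 91 in kidney, 88 in brain, 21 in lung and 15 in spleen. They held 63.3% of the restricted regions of liver, 49.8% of those of lung, 46.2% of those of kidney, 37.0% of those of brain and 11.7% of those of spleen. As many regions drawn at random 100 times from those with at least 20 reads gave at most 90 runs in liver, 12 in kidney, 6 in brain, 3 in spleen and 1 in lung. The folds of runs are of regions picked for being restricted, so their intervals do not cover that choice.

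Other runs were shorter. A kidney run on chromosome 2 from 124978186 to 125063086 spanned 84.9 kb and was 6.25-fold (5.71 to 6.86) over spleen, and one on chromosome 8 from 62988281 to 63026801 was 8.76-fold (7.48 to 10.3). Liver runs lay on chromosome 6 from 141577896 to 141640046, at 8.90-fold (7.85 to 10.1) over spleen, and on chromosome 12 from 7984316 to 8024816, at 16.9-fold (14.7 to 19.5). The lung run with the most regions covered 9.05 kb of chromosome 15 from 101097936 to 101106981 and was 8.48-fold (7.43 to 9.72) over brain. The spleen run with the most regions covered 24.0 kb of chromosome 12 from 114643246 to 114667206, with 2164 spleen reads, 7.97-fold (7.20 to 8.83) over lung. Spleen runs on chromosome 17 from 34428496 to 34442096 and on chromosome 6 from 70668611 to 70677551 were 5.09-fold (4.18 to 6.24) and 6.39-fold (5.20 to 7.89) over lung. The brain run with the most regions, on chromosome 2 from 136596221 to 136617371, was 4.42-fold (3.63 to 5.43) over spleen.

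**Figure D3:**
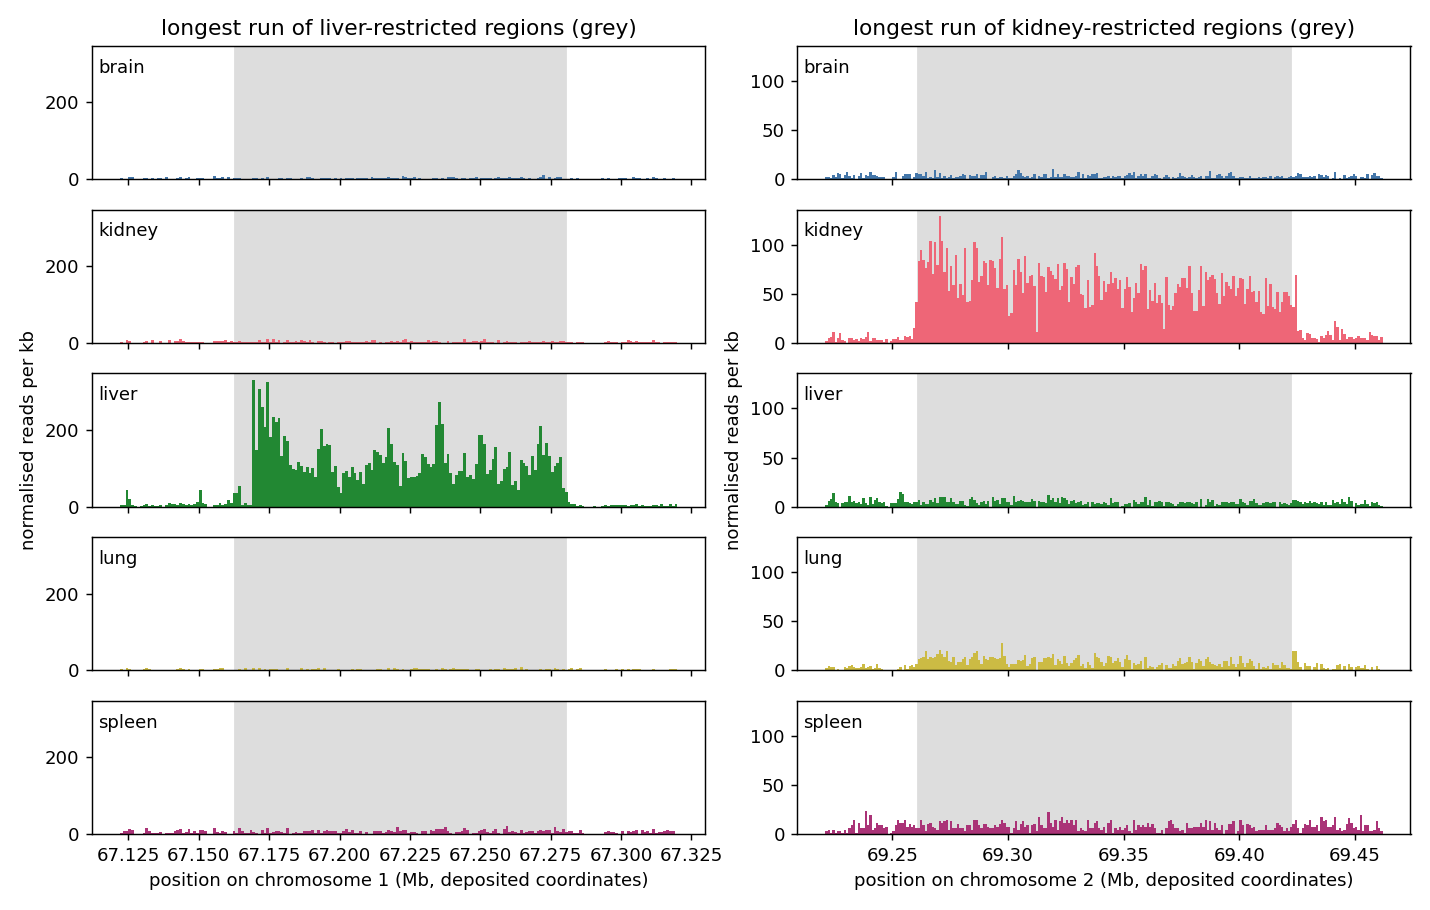
Normalised reads per kb (vertical axes, shared within each column) along the liver run on chromosome 1 (left) and the kidney run on chromosome 2 (right) with 40 kb on both sides; horizontal axes give deposited positions in Mb, each row is 1 tissue, and the run is shaded grey. Liver reads fill the left run, 15.6-fold over spleen, and kidney reads the right one, 6.81-fold over lung.

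Kidney and liver shared far more high regions than any other pair of tissues. In 482 regions both held at least 20 reads and at least 4-fold the normalised count of each of the other 3 tissues. Neighbouring regions were not joined for these counts of pairs, so they are not counts of separate places. The next pairs were kidney and lung with 41 regions and lung and spleen with 33, and the remaining 7 pairs had 2 to 12. With scaling by total reads, kidney and liver had 448 regions and kidney and lung 104. The region with the largest such fold lay on chromosome 4 from 49561991 to 49562656, with 206 reads in kidney, 1029 in liver and 2 to 7 in the other tissues; its lower normalised count, in kidney, was 30.6-fold over lung. Next on the same chromosome, the region from 49548156 to 49548656 held 106 reads in kidney, 75 in liver and 2 to 5 in the other tissues, and that from 49550206 to 49550706 held 62 in kidney, 93 in liver and 1 to 3 in the others.

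Neighbouring regions sometimes exchanged the lead between libraries. Among 22987 pairs of adjacent regions with midpoints 1 to 10 kb apart, the region holding the larger share of the reads differed between tissues in 2629 (11.4%), with exact binomial intervals that did not overlap. These intervals leave out the variation between libraries of 1 tissue, which was not measured here. With the same share in every tissue, counting error alone gave 188 such pairs on average and 220 at most in 100 simulations, which also leave that variation out. Whether both regions of a pair belong to the same gene was not examined, and adjacent regions of a run count in several pairs.

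Among pairs with at least 50 reads in both tissues, the largest exchanges were between liver and another tissue. The pairs named here were picked for a large difference in share, which their intervals do not cover. On chromosome 14, the region from 41938311 to 41938811 held 89.6% of the pair's liver reads (79.7% to 95.7%, 60 of 67) and 3.45% of its lung reads (0.420% to 11.9%, 2 of 58), the rest lying 6815 bp away at 41945056 to 41945696. On chromosome 11, the region from 120201301 to 120201946 held 83.3% (73.2% to 90.8%) in liver and 4.55% (1.69% to 9.63%) in lung. On chromosome 9, the region from 21048671 to 21049436 held 84.5% (72.6% to 92.7%) in brain and 10.2% (4.78% to 18.5%) in liver. On chromosome 2, the region from 164682316 to 164683156 held 97.3% (90.5% to 99.7%) in lung and 24.7% (16.2% to 35%) in liver, and that from 91476336 to 91476836 held 81.0% (74.5% to 86.5%) in liver and 9.43% (3.13% to 20.7%) in brain. A spleen example lay on chromosome 15 from 100499466 to 100500156, with 95.2% (86.5% to 99%) of the pair's reads in spleen and 25% (15.0% to 37.4%) in kidney.

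Polymerase reads were more sharply centred at regions common to all tissues than at restricted regions, a smaller contrast in spleen than in the other tissues. Among regions with at least 20 reads in the central window, the median density over that of the flanks at regions common to all tissues was 11.1-fold in brain (95% interval of the median over regions 10.8 to 11.3), 10.9-fold in lung, 9.64-fold in liver, 7.47-fold in spleen and 6.76-fold in kidney. At restricted regions it was 2.51-fold in brain (2.42 to 2.63), 2.22-fold in lung, 2.12-fold in liver, 2.09-fold in kidney and 5.08-fold in spleen (4.83 to 5.32). Regions with a peak in 1 tissue, restricted or not, were much like the restricted ones, at 2.36-fold in brain, 2.48-fold in lung, 2.04-fold in liver, 2.10-fold in kidney and 4.59-fold in spleen. The sets overlap, so this is not a separate observation. Of all restricted regions, 1002 of 1068 in brain and 148 of 217 in lung had a peak in that tissue alone. So had 3144 of 3649 in liver, 1318 of 1514 in kidney and 473 of 609 in spleen. Among regions with 40 to 79 central reads, the medians of common and restricted regions were 12.02-fold against 2.25-fold in liver, 15.0-fold against 3.66-fold in brain and 11.5-fold against 6.88-fold in spleen. The difference of the log2 medians of common and restricted regions grew after background subtraction, from 2.18 to 3.05 in liver and from 0.56 to 0.99 in spleen, an alternative chosen after the data were seen. Regions are not replicates, so these intervals describe the libraries alone. The flanks, 1 to 5 kb away, can hold other restricted regions of the same run, which lowers the ratio. Runs held 63.3% of the restricted regions of liver, 49.8% in lung, 46.2% in kidney, 37.0% in brain and 11.7% in spleen. How much of the contrast, or of its smaller size in spleen, comes from this was not tested.

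**Figure D4:**
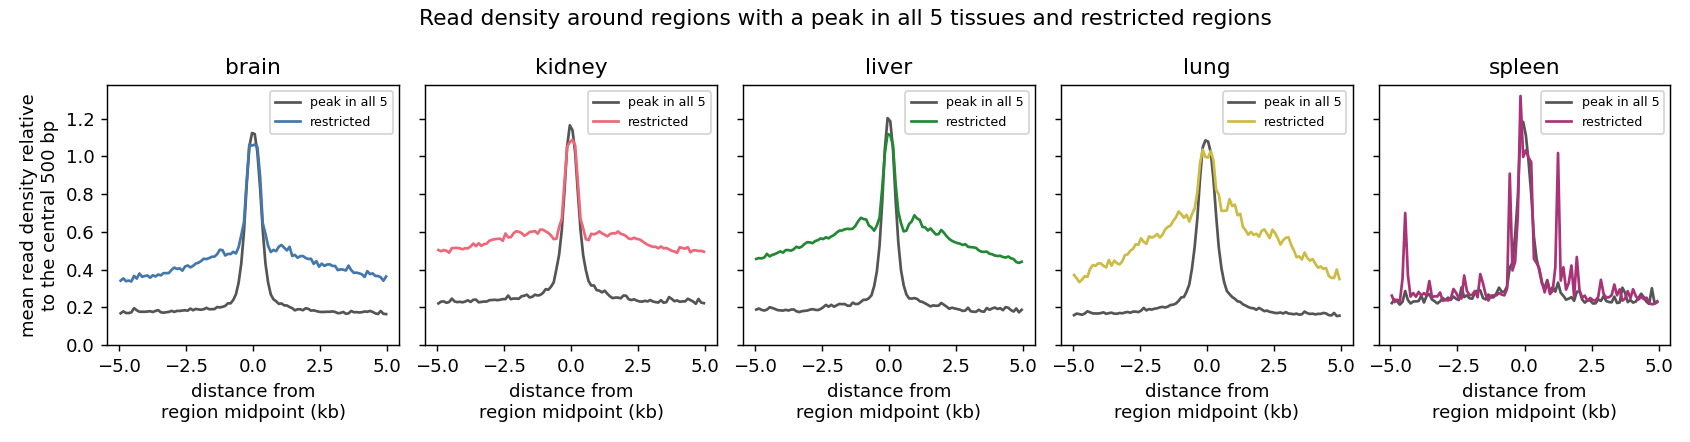
Mean read density by distance from the region midpoint (horizontal axes, kb), relative to the mean over the central 500 bp (vertical axis), for regions with a peak in all 5 tissues and for restricted regions of each tissue, without regions within 10 kb of 4 pile-up regions. Grey lines fall close to the midpoint in every tissue, while the restricted regions of brain, kidney, liver and lung keep higher flanks than those of spleen, whose curve has narrow spikes.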

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

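The comparison of Y reads between brain and spleen was chosen after the result was seen; the other 3 tests of the X pattern were chosen before theirs. Reads on chromosome Y outside peak regions are given because no comparison used them; each library held more than 3. There were 22 such reads in brain (95% exact Poisson interval 13.8 to 33.3), 67 in kidney (51.9 to 85.1), 72 in liver (56.3 to 90.7), 40 in lung (28.6 to 54.5) and 81 in spleen (64.3 to 101). Read density on Y was low in every library, from 0.00832 of that of the autosomes in lung to 0.0146 in spleen. The sex of the animals is not given in the labels used here.

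Read density on chromosome X relative to the autosomes also differed between tissues, from 0.457 in brain to 0.648 in spleen, with 0.508 in lung, 0.531 in kidney and 0.582 in liver. The values argue against a larger share of reads in autosomal peaks, since the highest ratio was still 1.35 times the lowest outside peak regions. In 100 kb windows without any peak region, the highest ratio was 1.30 times the lowest. There it was 0.532 in brain, 0.633 in lung, 0.677 in kidney, 0.684 in spleen and 0.694 in liver. This argues against weak signal outside the listed peaks for the brain library only. For differences among the other tissues, weak signal stays open. The values also argue against a brain library from males set beside a spleen library from females. Brain had 0.590 times the share of reads on Y of spleen (0.461 to 0.750), which counts only if Y sequence can be aligned in these data. Against background that follows peak density, the brain to spleen ratio of X lay at -4.71 residual SD from the line over the 19 autosomes, although X has 50.1 regions per Mb, fewer than the lowest autosome at 62.8, so that the line was extended beyond its range. A bias of the libraries by base composition was not tested, and with a difference in X chromatin between tissues it stays among the explanations that may apply.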

How the results depend on the processing

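The alternatives that rank peaks by reads, leave out the spleen library or the pile-up regions, rescale after background subtraction, set spleen and another tissue on the same regions, bear on kidney and liver together, set common against restricted regions, or bear on the read ratios at common regions were chosen after the data were seen. Of 200 recomputed folds of the named regions, 193 stayed inside the region's counting interval; none changed direction, which such high folds make unlikely. The 7 that moved include 5 of spleen regions, and 6 came with windows of 1000 bp to both sides. On the log2 scale, the spleen regions on chromosome 1, on chromosome 10 (at 42621186 and at 59682641) and on chromosome 11 then fell from 4.95 to 3.35, 4.32 to 2.67, 3.75 to 2.04 and 3.70 to 2.10, the brain region on chromosome 1 from 4.23 to 2.83 and the kidney region on chromosome 13 from 4.22 to 2.92. With total-read scaling, the spleen region on chromosome 9 fell from 3.97 to 2.92. Of the counts, shares, indices and medians below, 62 recomputed values were classed as staying near the reported ones and 126 as moved. The classes are not alike: indices had to stay inside a narrow interval, whereas counts were allowed larger changes. Restricted kidney regions at 2186 without the spleen library, against 1514, were classed as staying. A shared share of brain of 48.5%, against 49.0%, was classed as moved. Except where stated, the cause was not tested.

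The shares of regions with a peak in another tissue, for brain, kidney, liver, lung and spleen in this order, were 43.4%, 56.2%, 52.9%, 58.9% and 57.0% with 50% reciprocal overlap, and 52.4%, 68.4%, 64.9%, 71.1% and 64.4% with regions within 500 bp merged, as narrower and wider windows give by construction. They were 48.5%, 61.9%, 58.4%, 66.7% and 66.0% for the more-read 50% of each list, and 56.4%, 65.4%, 53.8%, 68.2% and 45.7% with equal numbers of peaks. With fewer peaks by construction, the more-read 50% gave 94475 regions, 5547 of them in all 5 tissues and 63961 in 1 tissue; equal numbers gave 89915 and 62545 in 1 tissue. The Jaccard index of brain with kidney, liver, lung and spleen, of kidney with liver, lung and spleen, of liver with lung and spleen, and of lung with spleen was 0.191, 0.141, 0.200, 0.115, 0.205, 0.245, 0.128, 0.178, 0.130 and 0.154 with 50% reciprocal overlap, 0.262, 0.200, 0.274, 0.166, 0.284, 0.342, 0.188, 0.253, 0.188 and 0.221 with regions within 500 bp merged, 0.237, 0.179, 0.262, 0.157, 0.258, 0.305, 0.173, 0.229, 0.185 and 0.214 for the more-read 50%, and 0.250, 0.201, 0.283, 0.190, 0.271, 0.311, 0.186, 0.237, 0.169 and 0.229 with equal numbers. Kidney and lung had the highest index under each. Brain and spleen had the lowest under all but equal numbers, where liver and spleen did. At regions common to all tissues, the median ratio of highest to lowest count was 2.86 with scaling by total reads, with 1848 regions at 4-fold, and 2.11 with 1 read per position and strand. Without the pile-up regions, 14.3%, 11.8%, 11.2%, 12.3% and 4.21% of reads lay near own peaks.

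Counts of restricted regions kept liver first under all settings but 1, no read minimum, where spleen led. Scaling by total reads gave 2144 in brain, 572 in lung and 179 in spleen, so that lung passed spleen and brain passed kidney. Background subtraction gave 1946 in brain and 393 in lung, and with its own scaling 2312 in kidney. Leaving out the spleen library gave 2017 in brain and 481 in lung. In spleen, 1 read per position and strand gave 393, of which 373 were among the 609, thinning to the smallest library gave 324, of which 297 were, and no read minimum gave 4152, since the floor of 3 reads asks for fewer reads in the library with the lowest scaling factor; of the 236 spleen regions lost with 1 read per position, 207 fell under 20 reads. For brain, kidney, liver, lung and spleen, a minimum of 50 reads left 179, 327, 1733, 94 and 73, a fold of 2 gave 3740, 5588, 8475, 1447 and 1800, and a fold of 8 left 75, 108, 1082, 20 and 131. A count close to the reported one can hold other regions: with windows of 1000 bp to both sides, spleen had 626, but only 222 of the 609 (36.5%) were kept, against 496 of 1068 (46.4%) in brain, 679 of 1514 (44.8%) in kidney, 140 of 217 (64.5%) in lung and 2852 of 3649 (78.2%) in liver. Regions high in kidney and liver rose to 1906 at 2-fold. Pairs of adjacent regions that exchanged the lead numbered 688 of 3411 (20.2%) at 3000 bp or more, 516 of 3440 (15%) with 50 reads, 2328 of 18212 (12.8%) after background subtraction and 1776 of 19479 (9.12%) with 1 read per position and strand, against 2629 of 22987 (11.4%).

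At all regions with a peak in the tissue and at least 20 central reads, median log2 centre over flank density for brain, kidney, liver, lung and spleen was 2.53, 1.66, 1.89, 2.71 and 2.83 with 1 read per position and strand, 2.39, 1.83, 2.03, 2.90 and 3.71 after background subtraction, and 3.98, 2.87, 3.17, 3.83 and 3.60 with 50 reads, against 2.12, 1.59, 1.73, 2.50 and 2.73. The median of common regions minus that of restricted regions, 2.15, 1.69, 2.18, 2.29 and 0.56 on this scale, became 2.78, 2.21, 3.05, 2.99 and 0.99 after background subtraction and 1.84, 2.25, 2.60, 2.80 and 0.65 with 50 reads, and stayed inside its bootstrap interval with 1 read per position and strand. It remained smallest in spleen under these 3 settings. Peaks have no score here, so the planned ranking by score was not run; nor were the alternatives for gene lists, gene-body reads, promoter sequence and annotated start sites. Of simulated regions at the 4-fold threshold itself, 16% were called; how this share varies with depth was not simulated.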

Other observations

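In the weighing of the spleen peaks, the comparisons of depth and of enrichment were chosen after the result was seen, and so were the draws matched on reads for the runs. Pairs of tissues other than kidney and liver also had regions of their own. Lung and spleen were both high in 33 regions, 32 with scaling by total reads. The leading one, on chromosome 11 from 87571766 to 87572311, held 89 reads in lung, 181 in spleen and 3 to 13 in brain, kidney and liver, and its lung count was 6.59-fold that of kidney after scaling. Kidney and lung were both high in 41 regions, led by chromosome 10 from 85771841 to 85772341 with 80 and 57 reads against 2 to 5 elsewhere. On chromosome 19, the region from 6534986 to 6535726 held 124 reads in brain, 105 in kidney and 18 in lung, and was 6.06-fold over lung.

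Of regions on chromosome X with at least 20 reads, 4 of 371 were restricted in brain (1.08%, 95% exact binomial interval 0.295% to 2.74%), 9 of 478 in kidney (1.88%, 0.864% to 3.54%) and 21 of 484 in liver (4.34%, 2.71% to 6.56%), against 3.98%, 3.98% and 10.8% of such regions on the other chromosomes. In spleen 15 of 216 were (6.94%, 3.94% to 11.2%) against 4.46%, and in lung 0 of 380 (interval up to 0.966%) against 0.815%, so both intervals include the value of the other chromosomes. These counts were made after the data were seen, and adjacent regions of a run are not independent. Of all brain peaks, 4.70% lay on X, against 4.44% in spleen, 3.37% in liver, 3.29% in lung and 2.95% in kidney.

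A few places collected very many reads in every library. The region on chromosome 2 from 98506421 to 98507471 held 8735 reads in brain, 15278 in kidney, 14651 in liver, 10451 in lung and 32756 in spleen. It was 1 of 4 regions with at least 1000 normalised reads in all tissues; the others lay on chromosome 2 from 98502571 to 98503096, on chromosome 9 from 35112611 to 35113256 and on chromosome 17 from 39982031 to 39983226. Together they held 0.148% of brain reads and 0.377% of spleen reads, and 1 restricted region, in spleen, lay within 10 kb of them. The most reads at 1 position and strand were 833 in spleen and 141 to 361 in the other libraries.

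Spleen had the fewest peaks, 31594, and a smaller library does not account for this. Spleen had 1.29 times the total reads of the smallest library, brain, which had the most peaks. Reads at regions with at least 20 reads in every tissue were nevertheless fewest in spleen by the scaling factors, 0.671 against 1.03 to 1.17 elsewhere. Lower enrichment over the local background was tested at regions with a peak in each of 3 tissues, neither spleen nor the tissue it was set against. The centre over flank ratio of spleen was 0.758 times that of brain (0.721 to 0.799), 0.757 times that of lung (0.700 to 0.800) and 0.780 times that of liver (0.740 to 0.822). It was 0.954 times that of kidney (0.902 to 1.01), which had 81375 peaks, so this local ratio does not tell spleen and kidney apart. Away from peak regions, density was 4.45 reads per kb in spleen and 3.91 in kidney. Just before the midpoint of regions common to all tissues, it was 57.0 in spleen and 82.1 in kidney. Over this wider background, the spleen library was therefore less enriched than the kidney library. At regions with a peak in each of the other 4 tissues but not its own, the centre over flank ratio was 1.42 in spleen, 1.41 in brain, 1.52 in kidney, 1.26 in liver and 1.38 in lung. Without an input library this does not show whether polymerase was there. Differences of tissue, chromatin or immunoprecipitation stay open with 1 library per tissue.

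Part of the restricted regions lay in runs, from 11.7% in spleen to 63.3% in liver, which had 310 runs. In liver, chance placement among read-rich regions gave at most 90 runs of at least 3 regions, fewer than were seen. Read number alone is also argued against, since draws with the same distribution of liver reads gave at most 128 runs. Both kinds of draws picked regions independently of their neighbours, so any signal that stretches over adjacent regions can exceed them. They do not show what joins the regions of a run. Transcription of long genes by elongating polymerase may give such runs in kidney and liver, a hypothesis that was not tested, since no gene annotation was used.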
